A study of Homo sapiens with 12 samples.

How the data were processed

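RNA was measured in 12 libraries of KKU-213A, a cell line of mixed papillary and non-papillary cholangiocarcinoma, 3 each from control, lactic acidosis, lactosis and acidosis cultures. Per the labels, poly(A) RNA was selected and sequenced as single-end reads of 75 nt. The submitters' processing notes name STAR and hg38. The tool that counted reads and its version are not stated.

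The authors deposited 3 tables, each setting 1 treated group against the same controls, with the column names of the EBSeq empirical Bayes test for 2 groups. In these deposited tables the per-library values are a signal, an expression value divided by gene length and scaled per library, and whether it is TPM or FPKM is not stated. The deposited group means are a signal as well, gene counts divided by size factors set within each table. The deposited fold changes are a ratio of control over treated, and were turned round so that a positive log2 fold change means higher in treated cells. The other deposited columns are posterior probabilities of equal and of different expression. Every listed gene had a probability of equal expression under 0.05. The highest was 0.0500 in lactic acidosis, 0.0500 in lactosis and 0.0497 in acidosis. Genes that were tested and not listed are in none of the tables, so they were not analysed here. No library totals are given, so read depth is unknown and no counting interval could be set. The control values were equal in all 3 tables, with a largest difference of 0, so per-library values were compared across tables.

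The gene counts of each treatment against control are the authors' calls. Gene lists were fixed before the data were examined, 32 in all, and each was tested by Fisher's exact test, two-sided, of listed higher against listed lower, with members set against all other listed genes. The 83 tests with a listed member were adjusted together by the Benjamini-Hochberg method, and 11 had an adjusted p under 0.05. The test treats genes as independent and does not match members to other genes by level. On simulated lists of 12 genes it gave p under 0.05 in 3.7% of 1000 lists with no direction and in 100.0% of 200 lists with 11 of 12 members lower. A further 3 lists were chosen after the data were seen.

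The per-library values of listed genes were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), without a filter, at an adjusted p under 0.05, separately for the 6 libraries of each comparison. For treated groups against each other, genes listed in both tables were tested. On simulated data with 200 genes changed by a log2 fold of 1, between 74.0% and 90.5% were recovered against control and at least 99.0% between treated groups. With a log2 fold of 0.5, 0.0% were recovered against control and between 81.5% and 86.5% between treated groups. All other simulated genes were unchanged, while in the data most listed genes passed against control, 3684 of 4279 in lactic acidosis. The adjustment was therefore stricter in the simulation, and the 0.0% does not show that listed changes of this size were missed. Library weights were fitted to the authors' group means to rescale the values as an alternative. Slopes are standardized major axis slopes with 1000 bootstrap resamples of genes, and the shared controls were studied with 100 simulations.

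Named genes followed a rule fixed before the data were examined. It took the 8 largest rises and falls per table with a group mean count of at least 10, up to 4 members per list by the authors' probability, 5 genes shared by all tables, 5 with opposite directions and 9 genes of interest. ALDH1A3 and EGFR were among these 9 because the study was known to have followed them up, so they are not independent evidence. Names of clones and of some non-coding RNAs were left out. Some genes that the rule or the lists would name are withheld and are not reported here. These genes were named outside that rule, after their values were seen: HLA-F, CIITA, HSPA1B, TGFB2, TNFSF18, VAV1, IL1A, SNX14, CTSB, MB, POTEI, MYH6, MYL3, TNNI2, TNNT3, HSPA8, HSPA2, DNAJA1, HSPH1, HSPB1, NCL, URB2 and NOLC1.

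Gene positions are from GENCODE release 29 on GRCh38. Shared sequence was measured as the percent of 40 windows of 75 bases per gene that occur in a transcript of another gene. Alternatives were stricter thresholds, pseudocounts of 0.1 and 5, filters on low values, the replicate number as a block, and leaving out each library in turn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.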

Results

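The series asked how long-term culture in lactate, in acid, or in both changed gene expression in KKU-213A, a human cholangiocarcinoma cell line, that is, a line from a cancer of the bile ducts. Polyadenylated RNA was sequenced in 12 libraries, 3 in each of 4 groups. Control cells grew in low-glucose medium. Lactic acidosis medium stood at pH 6.7, with L-lactate and the buffer HEPES at 25 mM each. Lactosis medium had the lactate alone, at pH 7.4, and acidosis medium the buffer alone, at pH 6.5. Treated cells had spent at least 5 passages in their medium. The pH of the lactic acidosis and acidosis media therefore differed, and the 3 treated groups shared the same 3 control libraries. HEPES is given only for the lactic acidosis and acidosis media, and passages only for treated cells. Acid therefore cannot be told apart from the buffer, against control or between lactic acidosis and lactosis. Nor can a treatment be told apart from time in its medium. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the tests below measure the spread between libraries, which may be technical.

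The authors deposited 1 table per treatment, which lists genes with a posterior probability of equal expression under 0.05 against control, with a length-scaled expression value for each library. Read depth is unknown from these tables. In the lactic acidosis table the deposited per-library values set treated over control 0.12 higher on the log2 scale than the size factors of the authors do, against 0.04 in lactosis and 0.02 in acidosis. Control replicate 1 had a fitted library weight of 1.000, against 0.791 and 0.769 in control replicates 2 and 3, so its deposited values lie low. Limma with a library left out used values that were not rescaled. Without control replicate 1, scale alone therefore moves treated over control downward. A gene that is absent from a table was not shown to be unchanged, since the genes that were tested and not listed were not analysed here. In the text, "listed higher" and "listed lower" give the direction in treated cells relative to control.

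Lactic acidosis was compared with control first. Of the listed genes, those of cholesterol synthesis, of the amino acid stress response, of the interferon response and of antigen presentation were all or mostly lower, and those of DNA replication were higher. In the authors' deposited table, 4279 genes were listed, 2521 higher and 1758 lower, and of the genes changed at least 2-fold, 448 were higher and 671 lower. DDIT3, a transcription factor of the stress response on chromosome 12 from 57516588 to 57521737 in GRCh38, averaged 454 ± 239 (SD, n = 3) in control libraries and 16.4 ± 1.12 (SD, n = 3) in lactic acidosis libraries. AKAP12, a scaffold protein for protein kinase A on chromosome 6 from 151239999 to 151358557, averaged 14.5 ± 8.95 (SD, n = 3) in control and 470 ± 20.6 (SD, n = 3) in lactic acidosis. The authors' deposited table gives log2 fold changes of -4.92 for DDIT3 and 4.98 for AKAP12.

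Cholesterol biosynthesis was the list with the smallest adjusted p. Of its 25 genes, 17 were listed lower, 1 was listed higher and 7 were not listed (Fisher's exact test of direction against the other listed genes, two-sided, adjusted p = 2.37e-04). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, averaged 35.7 ± 4.01 (SD, n = 3) in control and 9.56 ± 0.716 (SD, n = 3) in lactic acidosis. By the authors' deposited table the log2 fold change of INSIG1 was -2.01, that of MSMO1 was -1.24 and that of FDFT1, the squalene synthase gene, was -1.07. By limma on the per-library values, 14 of the 18 listed members passed when adjusted over all listed genes and 13 when adjusted over the list alone. SCD, a desaturase on the list of fatty acid synthesis, had a log2 fold change of -1.40 in the authors' deposited table, but that list had 2 members higher and 4 lower and did not pass (adjusted p = 0.502, Fisher's exact test).

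Of the 26 targets of ATF4, the transcription factor of amino acid stress, 6 were listed and all 6 were lower (adjusted p = 0.0361, Fisher's exact test). Besides DDIT3 these included NUPR1 and CHAC1, with log2 fold changes of -4.70 and -2.38 in the authors' deposited table. All 6 passed limma, both over all listed genes and when adjusted over the list alone. The control libraries themselves differed on this list: DDIT3 stood at 678.38, 480.78 and 202.53 in the 3 control libraries and NUPR1 at 234.53, 104.6 and 34.52. Every one of the lactic acidosis libraries lay below the lowest control for both genes.

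Of 24 genes of DNA replication, 12 were listed higher and none lower (adjusted p = 0.0297, Fisher's exact test), and 11 of them passed limma over all listed genes, against 12 adjusted over the list alone. Without lactic acidosis replicate 2, 6 of the 12 passed. Counted over genes past limma with the replicate number as a block, the list had 12 members higher and lost its call (adjusted p = 0.0794, Fisher's exact test). PCNA, the sliding clamp of DNA polymerase, averaged 199 ± 92.0 (SD, n = 3) in control and 448 ± 14.6 (SD, n = 3) in lactic acidosis. MCM10 and POLE2 had log2 fold changes of 1.52 and 1.26 in the authors' deposited table. On the list of mitosis genes, 2 of 22 were listed, both higher, which gave no call (adjusted p = 0.848, Fisher's exact test).

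All 8 listed members of the 24 interferon-stimulated genes were lower (adjusted p = 0.0222, Fisher's exact test), with IFIT2 at -1.47, IFIT3 at -1.03 and the chemokine CXCL10 at -1.99 in the authors' deposited table. These 8 include a gene that shares 100.0% of its 75-base windows with another transcript, so its listing is uncertain. On the antigen presentation list, 11 of 22 genes were listed lower and 2 higher (adjusted p = 0.0321, Fisher's exact test). CD74, the invariant chain of class II molecules, averaged 21.9 ± 3.13 (SD, n = 3) in control and 5.45 ± 0.289 (SD, n = 3) in lactic acidosis. HLA-F and CIITA, the master regulator of class II genes, had log2 fold changes of -1.79 and -2.36 in the authors' deposited table. The members listed higher were CD274, which encodes the checkpoint ligand PD-L1, at 2.22 and TAP2 at 0.37 in the authors' deposited table, and TAP2 shares 35.0% of its 75-base windows with an overlapping transcript. By limma, all 8 interferon-stimulated genes and 12 of the 13 antigen presentation genes passed, and the counts were 8 and 12 when adjusted over the list alone.

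The list of replication-dependent histones, fixed as a check on poly(A) selection, had 6 of 19 members listed, all lower (adjusted p = 0.0361, Fisher's exact test). HIST1H1C averaged 164 ± 14.6 (SD, n = 3) in control and 66.1 ± 4.57 (SD, n = 3) in lactic acidosis. These members were lower in the same libraries in which the listed replication genes were higher. Because the libraries were poly(A)-selected and the list was set as a check on that step, its direction cannot be read as a change in histone expression.

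Several lists of interest did not pass the test of direction against the other listed genes. Of 27 ERBB receptors, ligands and genes of MAPK feedback, 12 were listed higher and 3 lower (adjusted p = 0.389, Fisher's exact test). FOSL1, an AP-1 subunit on chromosome 11 from 65892049 to 65900573, averaged 105 ± 44.6 (SD, n = 3) in control and 691 ± 44.1 (SD, n = 3) in lactic acidosis. EREG, which encodes the EGFR ligand epiregulin, and the phosphatase genes DUSP4 and DUSP6 had log2 fold changes of 2.12, 2.08 and 1.52 in the authors' deposited table. EGFR itself was in none of the 3 tables. Of 31 mesenchymal and matrix genes, 12 were higher and 3 lower (adjusted p = 0.389, Fisher's exact test), with PLAUR at 1.80 in the authors' deposited table. Aldehyde dehydrogenases were listed in both directions, 3 higher and 7 lower of 18 (adjusted p = 0.372, Fisher's exact test). ALDH1A3, which makes retinoic acid and lies on chromosome 15 from 100877714 to 100916626, averaged 172 ± 80.9 (SD, n = 3) in control and 821 ± 30.0 (SD, n = 3) in lactic acidosis, with a log2 fold change of 2.20 in the authors' deposited table.

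Lists of genes that handle lactate, glucose and protons did not pass as groups in lactic acidosis. SLC16A1 and SLC16A3, the lactate transporter genes MCT1 and MCT4, had log2 fold changes of 0.25 and 0.45 in the authors' deposited table. The lactate dehydrogenase genes LDHA and LDHB and the lactate receptor gene HCAR1 were in none of the 3 tables. Glycolysis had 3 members higher and 5 lower of 20 (adjusted p = 0.566, Fisher's exact test), with ALDOC at -1.39 and GAPDH at -0.47 in the authors' deposited table. Of 22 genes of pH regulation, 5 were listed, all higher (adjusted p = 0.326, Fisher's exact test), and CA2, a cytosolic carbonic anhydrase, averaged 0.940 ± 0.262 (SD, n = 3) in control and 10.4 ± 0.217 (SD, n = 3) in lactic acidosis. TXNIP and ARRDC4, targets of the glucose sensor MondoA, had log2 fold changes of 2.07 and 1.83 in the authors' deposited table.

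**Figure D1:**
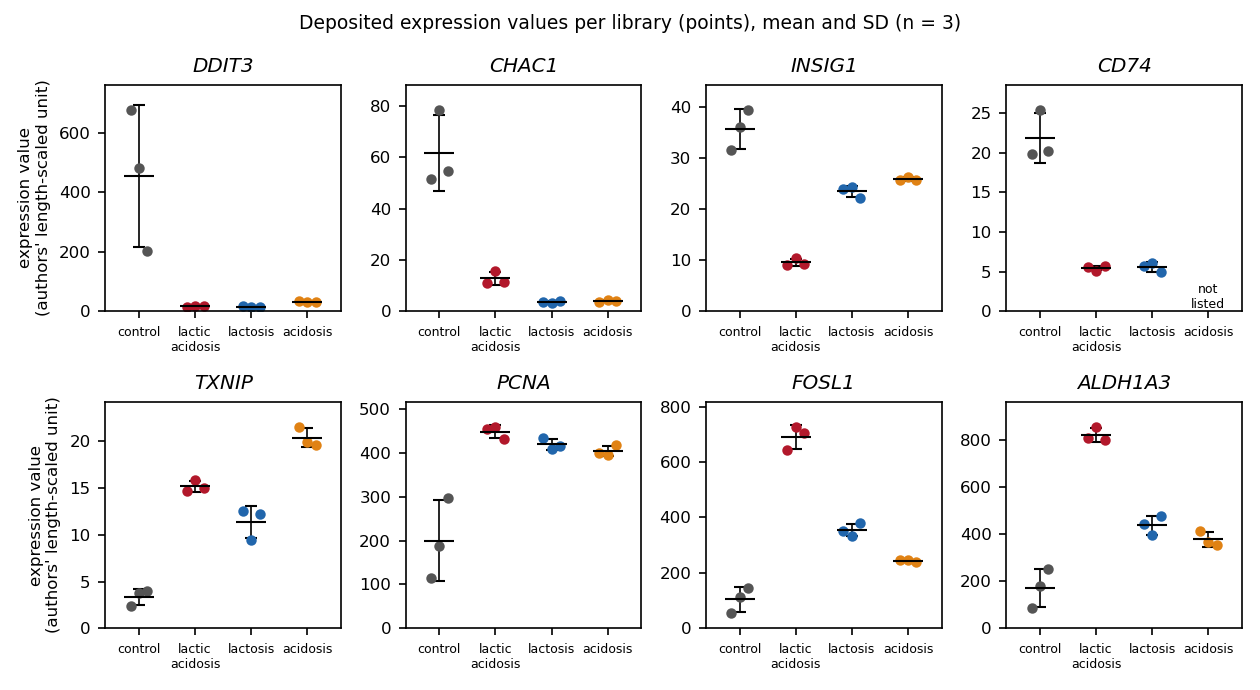
Each panel plots 1 gene, with the authors' length-scaled expression value on the vertical axis and the 4 groups on the horizontal axis; points are libraries and bars are the mean and SD (n = 3), and "not listed" marks a gene absent from that treatment's table. DDIT3 spread from 202.53 to 678.38 in the control libraries and lay at 34.95 or below in every treated library.

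Among the largest rises and falls were genes that need care. KRTAP2-3, a keratin-associated protein gene, averaged 1.62 ± 0.779 (SD, n = 3) in control and 61.3 ± 2.92 (SD, n = 3) in lactic acidosis, and 35.0% of its windows also occur in related genes. PCDH10, a protocadherin gene, stood at 0.37, 0.32 and 0.44 in the control libraries and is listed at 0 in all 3 lactic acidosis libraries. IP6K3, FIBIN, TRPV6 and SAMD11 averaged between 1.16 and 3.02 in control and at most 0.0900 in lactic acidosis. CST4, a salivary cystatin gene, averaged 0.327 ± 0.284 (SD, n = 3) in control and 6.65 ± 0.841 (SD, n = 3) in lactic acidosis. EIF3CL, GTF2H2C, TMX2-CTNND1 and TRIM6-TRIM34 share 100.0%, 82.5%, 85.0% and 97.5% of their windows with another gene, so their listing is uncertain. MYH1 and MYH2, myosin genes of skeletal muscle, stood at 1.2 and 1.48 in lactic acidosis replicate 2 and at 0.07 or below in the other lactic acidosis libraries and in control.

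The listed genes were chosen on these same libraries, so a limma test of them is a description of the spread and not independent evidence; 3684 of the 4279 passed (2368 higher, 1316 lower). Counted over genes with a posterior probability under 0.01, the ATF4 and DNA replication lists both had adjusted p = 0.0748 (Fisher's exact test). Over genes changed at least 2-fold, no list called in any of the 3 comparisons kept its call. In lactic acidosis 448 higher and 671 lower genes were counted there. Cholesterol had 0 members higher and 7 lower, and DNA replication 4 higher and 0 lower. The histones had 0 members higher and 6 lower in both counts, but adjusted p went from 0.0361 to 0.544 (Fisher's exact test). Of all listed genes in lactic acidosis 2521 were higher and 1758 lower, while most genes changed at least 2-fold were lower. A list of lower members then stands out less. DNA replication had fewer members, 4 against 12. These losses therefore do not show that list members changed direction.

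Lactosis was compared with control to see what lactate did without acid. The listed ATF4 targets, DDIT3 and CHAC1 among them, and the listed targets of the hypoxia-inducible factors were lower, as were most listed genes of antigen presentation, while FOSL1, AKAP12 and ALDH1A3 were listed higher. The authors' deposited table listed 3087 genes, 1830 higher and 1257 lower, of which 250 were higher and 394 lower by at least 2-fold. CHAC1, which degrades glutathione, averaged 61.5 ± 14.8 (SD, n = 3) in control and 3.50 ± 0.447 (SD, n = 3) in lactosis. AKAP12 averaged 169 ± 34.6 (SD, n = 3) and ALDH1A3 438 ± 40.9 (SD, n = 3) in lactosis.

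All 7 listed ATF4 targets were lower (adjusted p = 0.0297, Fisher's exact test), and DDIT3, CHAC1 and SESN2, a stress-induced inhibitor of mTORC1, had log2 fold changes of -5.07, -4.15 and -2.76 in the authors' deposited table. Of 22 antigen presentation genes, 8 were listed lower and 1 higher (adjusted p = 0.0361, Fisher's exact test), with CD74 at -2.02, HLA-F at -1.55 and, as the member listed higher, CD274 at 1.62 in the authors' deposited table. All 6 listed targets of the hypoxia-inducible factors, of 23 on the list, were lower (adjusted p = 0.0361, Fisher's exact test). VEGFA, a growth factor for blood vessels, averaged 159 ± 27.9 (SD, n = 3) in control and 61.6 ± 3.50 (SD, n = 3) in lactosis, and CA9, an extracellular carbonic anhydrase, averaged 5.57 ± 3.07 (SD, n = 3) and 1.00 ± 0.0400 (SD, n = 3). Every listed member of these 3 lists, 7, 9 and 6 genes, passed limma over all listed genes and when adjusted over the list alone. When the lists were counted over genes past limma without control replicate 1, the ATF4 targets kept their call (adjusted p = 0.0434, Fisher's exact test). Antigen presentation and the hypoxia targets had adjusted p = 0.0957 and 0.0764 in the same test. All their members were still counted, in the same directions, while the share of higher genes among all those counted went from 59.3% to 52.6%.

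Other groups did not pass in lactosis. Of 24 DNA replication genes, 12 were listed higher and 1 lower (adjusted p = 0.118, Fisher's exact test), with PCNA at 1.09 and CCNE1, which encodes cyclin E1, at 1.55 in the authors' deposited table. Cholesterol biosynthesis had 2 members higher and 5 lower of 25 (adjusted p = 0.389, Fisher's exact test), with INSIG1 at -0.62 in the authors' deposited table. All 4 listed interferon-stimulated genes were lower (adjusted p = 0.134, Fisher's exact test). Of the ERBB and MAPK feedback genes, 6 were higher and 3 lower (adjusted p = 0.911, Fisher's exact test), with FOSL1 at 1.76 and DUSP6 at 1.08 in the authors' deposited table. The mesenchymal list had 8 members higher and 2 lower (adjusted p = 0.472, Fisher's exact test). SLC16A1 and SLC16A3 had log2 fold changes of 0.22 and 0.27 in the authors' deposited table, and neither passed limma (adjusted p = 0.124 and 0.0852). Without control replicate 1, the limma log2 difference of SLC16A3 went from 0.31 to 0.17.

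The largest changes in lactosis again included stress genes and genes of low level. INHBE, a secreted inhibin subunit, averaged 7.52 ± 3.86 (SD, n = 3) in control and 0.203 ± 0.125 (SD, n = 3) in lactosis, and ADM2, which encodes a peptide of the calcitonin family, averaged 2.79 ± 1.54 (SD, n = 3) and 0.110 ± 0.0300 (SD, n = 3). CYP26A1, a retinoic acid hydroxylase, and SNAI3 averaged 2.11 ± 0.188 and 2.10 ± 0.0153 in control and 0.0933 ± 0.121 and 0.0767 ± 0.0681 in lactosis (SD, n = 3), and 30.0% of the CYP26A1 windows occur in another transcript. KRTAP2-3 averaged 31.4 ± 3.11 (SD, n = 3). SMN2, SYS1-DBNDD2 and TRIM6-TRIM34 share 95.0%, 95.0% and 97.5% of their windows with other genes, and UBE2F-SCLY shares most of its windows. The muscle genes CKM, MYH7, DES, ACTC1 and ACTA1 were listed higher on the strength of lactosis replicate 2, where CKM stood at 8.29 against 0 and 0.1 in the other lactosis libraries and 0.14 at most in control. By limma, 2398 of the 3087 listed genes passed (1435 higher, 963 lower), and 2589 passed without control replicate 1 (1361 higher, 1228 lower). Without lactosis replicate 2 the count was 1764, and without lactosis replicates 1 or 3 it was 1423 or 1515, the latter with 756 higher and 759 lower.

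Acidosis, that is, acid together with HEPES and without added lactate, was compared with control. The listed cholesterol genes and ATF4 targets were lower, and TXNIP, HSPA1A and several EGFR-pathway genes were listed higher. The authors' deposited table listed 1721 genes, 1051 higher and 670 lower, with 69 higher and 146 lower by at least 2-fold. TXNIP, which lies on chromosome 1 from 145992435 to 145996600 and encodes an inhibitor of glucose uptake, averaged 3.38 ± 0.841 (SD, n = 3) in control and 20.4 ± 1.03 (SD, n = 3) in acidosis.

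Of 25 cholesterol genes, 11 were listed and all 11 were lower (adjusted p = 0.00123, Fisher's exact test). LSS, MSMO1 and INSIG1 had log2 fold changes of -0.74, -0.26 and -0.47 in the authors' deposited table. By limma, 7 of the 11 passed over all listed genes and 8 when adjusted over the list alone, against 4 over all listed genes without acidosis replicate 2. All 5 listed genes of fatty acid synthesis were lower without a call (adjusted p = 0.0566, Fisher's exact test), among them SCD at -1.14 in the authors' deposited table. All 7 listed ATF4 targets were lower (adjusted p = 0.0276, Fisher's exact test), and all 7 passed limma on both adjustments, the second being adjusted over the list alone. DDIT3 averaged 31.5 ± 3.04 (SD, n = 3) in acidosis and SLC7A11, the cystine transporter gene, averaged 40.1 ± 11.2 (SD, n = 3) in control and 8.88 ± 2.56 (SD, n = 3) in acidosis. Counted over genes past limma without control replicate 1, the ATF4 list had adjusted p = 0.0957 and the cholesterol list 0.0304 (Fisher's exact test). All 7 ATF4 targets were still counted, all lower, while the share of higher genes among all those counted went from 61.1% to 47.0%. With the replicate number as a block in limma, 5 cholesterol genes were counted, all lower, and the list lost its call (adjusted p = 0.0870, Fisher's exact test).

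All 10 listed DNA replication genes were higher (adjusted p = 0.0566, Fisher's exact test), as were all 8 listed ERBB and MAPK feedback genes (adjusted p = 0.134, Fisher's exact test), with PCNA at 1.06, FOSL1 at 1.21 and EREG at 0.98 in the authors' deposited table. By limma 7 of the 10 and 8 of the 8 passed, against 6 and 3 without acidosis replicate 2. The 3 listed interferon-stimulated genes, IFIT1, DDX58 and CXCL10, were higher, at 0.96, 0.40 and 0.75 in the authors' deposited table, without a call for the list (adjusted p = 0.566, Fisher's exact test). By limma DDX58 did not pass (adjusted p = 0.0891), and without control replicate 1 the log2 difference of IFIT1 went from 0.93 to 0.58 and that of CXCL10 from 0.73 to 0.38, both still past the threshold. Without acidosis replicate 2, 1 of the 3 passed. None of the 19 lactate and pyruvate genes was listed. ALDH1A3 averaged 378 ± 31.5 (SD, n = 3) in acidosis.

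IL13RA2, a decoy receptor for interleukin 13, averaged 0.723 ± 0.178 (SD, n = 3) in control and 3.72 ± 0.560 (SD, n = 3) in acidosis, and CLDN11, a tight junction gene, averaged 3.23 ± 2.13 (SD, n = 3) and 11.6 ± 0.823 (SD, n = 3), with 22.5% of its windows shared. HSPA1A, an inducible heat shock protein gene that shares 70.0% of its windows, chiefly with HSPA1B, averaged 80.1 ± 32.3 (SD, n = 3) and 379 ± 8.02 (SD, n = 3). GPNMB, a glycoprotein gene of the lysosome, averaged 8.63 ± 1.29 (SD, n = 3) in control and 0.650 ± 0.356 (SD, n = 3) in acidosis, and GPR1, INHBE, ADM2 and FIBIN were also among the largest falls. ATP5J2-PTCD1, TMX2-CTNND1, TICAM2 and ATP6V1B1-AS1 share at least 70.0% of their windows with other genes. By limma, 1033 of the 1721 listed genes passed (617 higher, 416 lower), 1682 passed once the values were rescaled to the authors' size factors, and 656 passed (378 higher, 278 lower) with the replicate number as a block. Without control replicate 2 or acidosis replicates 1, 2 or 3, 526, 543, 425 or 586 passed. The balance of directions turned without acidosis replicate 1 (194 higher, 349 lower) and without control replicate 1 (581 higher, 655 lower). Fitted library weights were 1.000, 0.791 and 0.769 in the control libraries and 0.771, 0.859 and 0.890 in the acidosis libraries. On values not rescaled, leaving out either library moves treated over control downward by scale alone. Rescaling was not combined with leaving out a library.

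**Figure D2:**
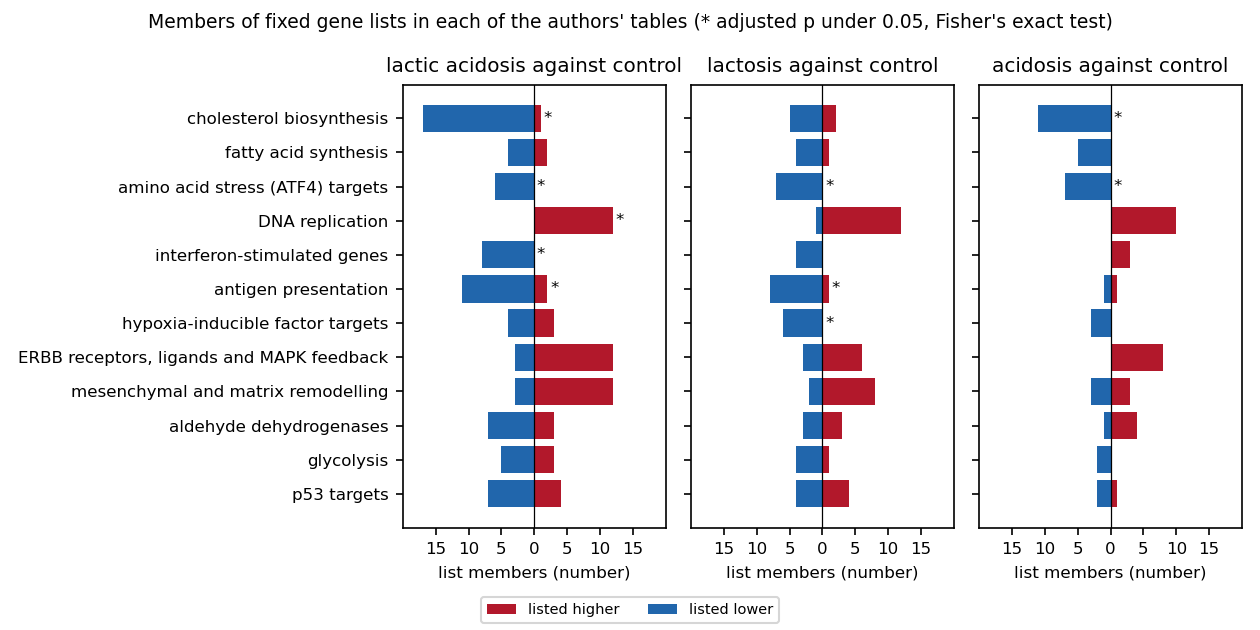
Bars count the members of 12 gene lists that each of the authors' tables lists higher (right, red) or lower (left, blue), with 1 panel per treatment and the number of members on the horizontal axis; an asterisk marks an adjusted p under 0.05 by Fisher's exact test of direction. Cholesterol biosynthesis shows 17 members lower in lactic acidosis, 5 in lactosis and 11 in acidosis.

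The tables were then compared with each other. Lactic acidosis and lactosis had 2344 listed genes in common, of which 1438 were higher and 898 lower in both, and 8 had opposite directions. Lactic acidosis and acidosis had 1304 in common (806 higher and 478 lower in both, 20 opposite), and lactosis and acidosis 1173 (738 and 421, 14 opposite). All 3 tables listed 1042 genes, and 1034 of these had 1 direction throughout, 670 higher and 364 lower. DDIT3, FIBIN, GPR1, PRPH and INHBE had the largest shared changes by the smallest of their 3 fold changes, all falls. DDIT3 had log2 fold changes of -4.92, -5.07 and -3.88 in the authors' deposited table of lactic acidosis, lactosis and acidosis. All 5 had uneven controls, highest in replicate 1 and lowest in replicate 3. FIBIN stood at 3.02, 1.36 and 0.23 in the control libraries, GPR1 at 10.02, 4.28 and 1.15, and PRPH, which encodes peripherin, at 2.3, 0.75 and 0.06. By limma PRPH did not pass in lactic acidosis (adjusted p = 0.0673) or lactosis (adjusted p = 0.0556), and in acidosis it passed (adjusted p = 0.0284) but not without control replicate 1 (adjusted p = 0.0834). FIBIN in lactic acidosis moved from -1.17 to -0.75 by limma without control replicate 1, and passed both times.

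Part of this overlap is built in, because the 3 comparisons share their controls. Across genes, which are not independent replicates, the fold changes on the per-library values correlated with Pearson's r = 0.95, 0.91 and 0.93 and Spearman's rho = 0.93, 0.89 and 0.90 for the 3 pairs in the order above. Simulated unchanged groups against the same controls gave Pearson's r = 0.68, 0.69 and 0.68, with 71.6%, 72.0% and 71.9% of genes in 1 direction, against 99.6%, 98.5% and 98.8% observed. The covariance was 0.66, 0.52 and 0.49, against 0.034, 0.031 and 0.033 simulated. The simulation made no calls, while the observed genes had been listed in both tables against these controls. Such a choice raises the agreement by itself, so the simulated values are not a full baseline. With 3 controls the group cannot be split to keep 2 libraries on each side. Part of the excess may therefore come from the shared controls, besides the choice of listed genes. The overlap of independent lists could not be computed, since the number of genes tested is not in the tables.

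In the authors' deposited tables, shared changes were largest in lactic acidosis. The standardized major axis slope of lactic acidosis on lactosis was 1.10 (95% bootstrap interval over genes 1.07 to 1.13), and on acidosis 1.39 (1.32 to 1.47). Of the 1034 genes with 1 direction, 592 had their largest change in lactic acidosis, 342 in lactosis and 100 in acidosis.

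**Figure D3:**
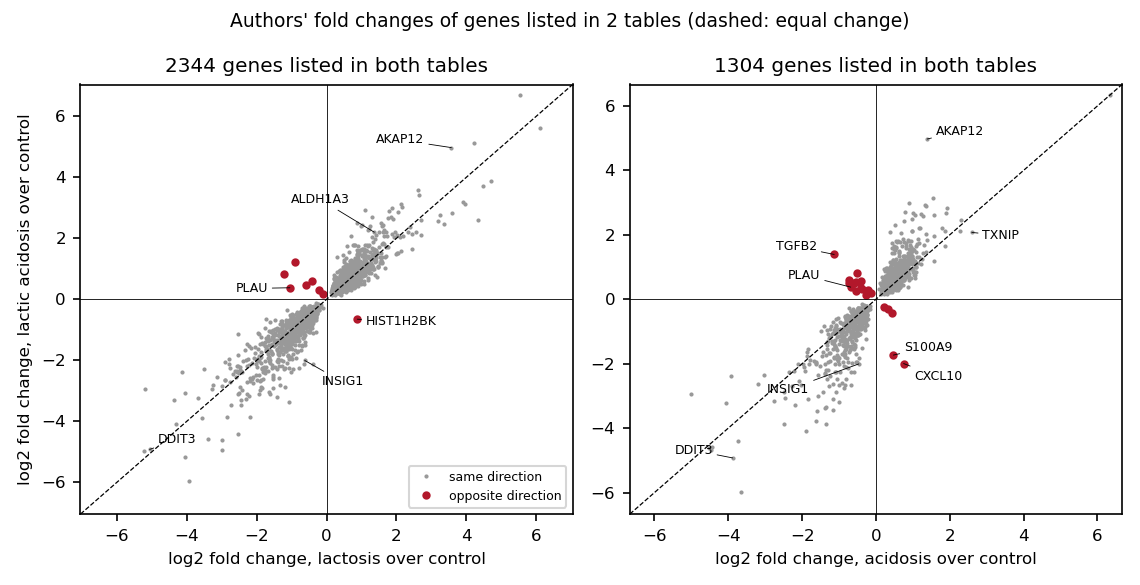
Each point is a gene listed in both tables, with the authors' log2 fold change in lactic acidosis on the vertical axis and in lactosis (left, 2344 genes) or acidosis (right, 1304 genes) on the horizontal axis; the dashed line marks equal change and red marks opposite directions. The 8 and 20 red points include PLAU in both panels and CXCL10, TGFB2 and S100A9 on the right.

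The treated groups were tested against each other with limma on the genes listed in both tables. FOSL1, DUSP4 and ALDH1A3 were higher in lactic acidosis than in lactosis, and INSIG1 and FDFT1 were lower. The log2 difference (value + 1) was 0.91 ± 0.09 (SE) for ALDH1A3, 0.96 ± 0.09 for FOSL1, 1.46 ± 0.09 for DUSP4 and 1.49 ± 0.13 for AKAP12. INSIG1 differed by -1.22 ± 0.08 (SE) and FDFT1 by -0.69 ± 0.08. Of 2344 genes, 479 differed, 367 higher and 112 lower in lactic acidosis, and after rescaling to the authors' size factors 553 differed, 348 higher and 205 lower. Among list members, 4 of the 6 cholesterol genes tested were lower in lactic acidosis, and 5 of 9 ERBB and MAPK genes and 6 of 10 mesenchymal genes were higher, with none in the other direction. Some falls were smaller in lactic acidosis than in lactosis. Of the ATF4 targets and interferon-stimulated genes, all listed lower against control in both, 3 of 5 and 3 of 4 tested were higher in lactic acidosis and 0 lower. After rescaling, 3 and 2 were higher. PLAU, the urokinase gene, averaged 326 ± 21.8 (SD, n = 3) in control, 458 ± 22.9 (SD, n = 3) in lactic acidosis and 161 ± 19.0 (SD, n = 3) in lactosis. The count fell to 259, 318 or 286 without lactic acidosis replicates 2, 1 or 3 and to 296 without lactosis replicate 1.

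Against acidosis, lactic acidosis showed higher DUSP4 and AKAP12 and lower cholesterol genes and CXCL10. The log2 difference was 1.78 ± 0.09 (SE) for DUSP4, 3.66 ± 0.14 for AKAP12 and 1.12 ± 0.08 for ALDH1A3. CXCL10 differed by -2.25 ± 0.13 (SE), INSIG1 by -1.35 ± 0.08 and TXNIP by -0.40 ± 0.07. Of 1304 genes, 636 differed, 505 higher and 131 lower in lactic acidosis, and 618 after rescaling, 415 higher and 203 lower. Of 11 cholesterol genes tested 6 were lower and none higher, of 7 ERBB and MAPK genes 6 were higher, and all 5 mesenchymal genes tested were higher. No direction counts of a whole list passed a test between 2 tables after adjustment. The smallest p was 0.00606 for the interferon-stimulated genes, 8 lower in lactic acidosis and 3 higher in acidosis (adjusted p = 0.467, Fisher's exact test). That test treats the 2 tables as independent, though they share genes and controls. Its counts are also small, so it cannot show that directions were equal.

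Between lactosis and acidosis, 280 of 1173 genes differed, 192 higher and 88 lower in lactosis, and 380 after rescaling, 239 higher and 141 lower. AKAP12 differed by 2.17 ± 0.19 (SE) on the log2 scale and FGF5, a fibroblast growth factor gene, by 1.24 ± 0.09. DDIT3 differed by -1.12 ± 0.12 (SE), TXNIP by -0.79 ± 0.11 and VEGFA by -0.32 ± 0.08. For ALDH1A3 the difference of 0.21 ± 0.10 (SE) did not pass (limma adjusted p = 0.159). The count was 156 without lactosis replicate 1 and 131 without acidosis replicate 2.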

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

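The treated groups differed from each other beyond the spread between libraries by limma in 479 genes for lactic acidosis against lactosis, 636 for lactic acidosis against acidosis and 280 for lactosis against acidosis. The tests of the ATF4 list, of control replicate 1, of the muscle genes, of all genes with opposite directions and of other splits of the libraries were chosen after the result was seen, while those of transcript length and of shared sequence were set beforehand. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 split of 10 with as many genes in each comparison. Against control the genes tested had been listed for differing on the real split, and every other split mixes treated and control libraries, so low counts there follow from that choice. The highest of the other splits gave 0 genes against 3684 in lactic acidosis, 1 against 2398 in lactosis and 7 against 1033 in acidosis, and 0 in each comparison of treated groups.

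Of the genes listed in opposite directions in 2 tables, 8 of 8 differed by limma's test of the difference between lactic acidosis and lactosis, 20 of 20 between lactic acidosis and acidosis and 13 of 14 between lactosis and acidosis, where CTSB did not (adjusted p = 0.0827). These genes were picked because the same libraries put them on opposite sides of the same controls, so a difference was nearly fixed by that choice and the counts are not independent evidence of it. Between lactic acidosis and lactosis, on the log2 scale (value + 1), TNFSF18, a ligand of the tumour necrosis factor family, differed by 2.13, VAV1 by 1.58, PLAU by 1.51, IL1A by 1.15, ERRFI1, an inhibitor of EGFR, by 1.09, SNX14 by 0.55 and CTSB by 0.33, all higher in lactic acidosis. The histone gene HIST1H2BK, which shares 52.5% of its windows with other histone genes, differed by -1.45. Among named genes between lactic acidosis and acidosis, TGFB2 differed by 2.06, ERRFI1 by 1.43, MTRNR2L8 by 1.40, PLAU by 1.16 and CDH1, the E-cadherin gene, by 0.78, while CXCL10 differed by -2.25 and S100A9 by -2.01. Among named genes between lactosis and acidosis, HIST1H2BK differed by 1.33, MTRNR2L8 by 0.95 and S100A9 by -1.30.

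The control libraries differed from each other along the direction of the treatment changes. Across listed genes, control 3 minus control 2 correlated with lactic acidosis minus control 1 with a Spearman rho of 0.53. With lactosis in place of lactic acidosis rho was 0.59, and with acidosis it was 0.71. Transcript length is argued against, since rho was 0.53 (95% interval over genes 0.50 to 0.55) in lactic acidosis after the length trend was taken out. It was then 0.58 in lactosis and 0.68 in acidosis. For the listed genes, control 1 alone is argued against as the basis of the calls in lactic acidosis, since 95.0% passed limma without it. In lactosis 2589 of 3087 and in acidosis 1236 of 1721 passed. These genes had been chosen on the same libraries, which favours a high share. How control 1 affected which genes were listed cannot be seen. Of the 11 list calls, 3 were lost. Adjusted p was 0.0764 (hypoxia targets) and 0.0957 (antigen presentation) in lactosis and 0.0957 (ATF4 targets) in acidosis, by Fisher's exact test. Every listed member of these 3 lists still passed limma in its direction. The share of higher genes among all those counted went from 59.3% to 52.6% in lactosis and from 61.1% to 47.0% in acidosis. These values were not rescaled, and leaving out control 1 then moves treated over control downward by scale alone. The lost calls therefore do not show that the changes of these members rest on control 1. Whether the control cultures differed in amino acid stress stays open: the ATF4 list members that fell lay 0.85 higher in control 1 than in control 3 at the median, against 0.15 for other genes that fell, a difference of 0.70. That sets 1 library against 1 and restates values of DDIT3 and NUPR1 already seen, so it decides nothing.

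Muscle genes such as CKM, ACTA1 and MYL3 were highest in replicate 2 within lactic acidosis and within lactosis, in 8 of the 9 listed muscle genes in lactic acidosis (the exception was MB) and 8 of 8 in lactosis. In lactic acidosis 6 of the 9 were listed higher than control and 3 lower, MB, TNNI2 and TNNT3, and in lactosis all 8 were listed higher. A response to lactate stays open: replicates 1 and 3 lay above every control for 0 of the 4 muscle genes listed in both tables in lactosis and for 2 of 4 in lactic acidosis, at levels near 0. RNA or reads from muscle in these libraries stays open too: the ratio of lactic acidosis 2 to lactosis 2 ran from 0.48 to 0.59 over the 4 genes, a range of 1.24 times, but MB goes against it, and both tests used the genes that showed the pattern. Levels were low, with CKM at 8.29 and ACTA1 at 28.35 in lactosis replicate 2.

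Some listed genes stood at 0 in a library and at 1 or more in another of the same group, 22 in all, such as SMN2, EIF3CL and GTF2H2C. Reads shared between near-identical genes or read-through transcripts may account for many of them. The 19 with a transcript in the annotation had a median of 85.0% of windows in common with another gene, against 0.0% for the other listed genes, and a mean of 61.7% against 4.2% (permutation p of the difference in means = 1e-05, the smallest the permutations can give). In 12 of the 19 the share was over 50%, and the remaining genes were POTEI and 6 muscle genes. No biological explanation was tested.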

How the results depend on the processing

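The rescaling, the limma tests, the counts without control replicate 1 and the removal of shared sequence were chosen after seeing the data. The cause of each change below was not tested, except that stricter settings test fewer genes and left-out libraries leave fewer samples. Both also change the genes that a list is set against. Tests on counts of all genes (edgeR, DESeq2) and the set tests camera and fry were planned but not run, since counts and unlisted genes are not in the tables; a fit of all 12 libraries was not run because the listed genes differ between tables; and 3 controls cannot be split with 2 on each side. Depth is unknown, so what it limits cannot be stated.

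Of genes changed at least 2-fold there were 1119 in lactic acidosis, 644 in lactosis and 215 in acidosis, with overlaps of 453 (lactic acidosis and lactosis), 146 (lactic acidosis and acidosis) and 125 (lactosis and acidosis). Genes above the median level numbered 2139, 1543 and 860, with overlaps of 1230, 696 and 634. Of the genes above the median, 74.7% were higher in lactic acidosis, 70.7% in lactosis and 70.7% in acidosis. Among all listed genes the shares were 58.9%, 59.3% and 61.1%. Direction thus went with level, and the list tests did not match members for level. The slope of lactic acidosis on acidosis was 1.30 over genes changed at least 2-fold. By limma, leaving out 1 library gave 2624 to 4064 genes in lactic acidosis, 1423 to 2589 in lactosis and 425 to 1251 in acidosis, where the replicate block gave 656 and rescaling 1682. For treated groups the ranges were 259 to 663 for lactic acidosis against lactosis, 485 to 759 for lactic acidosis against acidosis and 131 to 335 for lactosis against acidosis.

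At a probability under 0.01, 7 lists were called; adjusted p was 0.0748 for the ATF4 and DNA replication lists in lactic acidosis and the ATF4 list in acidosis, and 0.148 for the hypoxia targets in lactosis. Over genes changed at least 2-fold 1 list was called, none of the 11. Adjusted p in lactic acidosis was then 0.422 (cholesterol), 0.583 (ATF4, interferon and antigen presentation), 0.375 (DNA replication) and 0.544 (histones). In lactosis it was 0.583 (hypoxia), 0.544 (ATF4) and 0.912 (antigen presentation), and in acidosis 1.00 (cholesterol) and 0.607 (ATF4). With the replicate block it was 0.0794 for DNA replication in lactic acidosis and 0.0870 for cholesterol in acidosis. Without control replicate 1 it was 0.0764 for hypoxia and 0.0957 for antigen presentation in lactosis and 0.0957 for ATF4 in acidosis, each with all its listed members still counted in the same direction. All p here are from Fisher's exact test.

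Of 481 fold changes of named genes, 300 kept their direction and limma's threshold under every alternative run, 172 missed the threshold under some, and 9 changed sign. With 1 library left out, ACTA1 ran from -0.13 (without lactic acidosis replicate 2) to 1.80 in lactic acidosis. In lactosis the lowest values came without lactosis replicate 2, with ACTA1 from -0.21 to 2.01, ACTC1 from -0.07 to 0.93, CKM from -0.08 to 1.53, DES from -0.17 to 1.30, MYH6 from -0.01 to 0.48, MYL3 from -0.04 to 1.45 and POTEI from -0.07 to 0.82. CTSB in lactosis ran from -0.15 to 0.01, the latter without control replicate 3.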

Other observations

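The lists in this part, and the test of them, were chosen after the data were seen. Genes above the median level were more often higher, 74.7% in lactic acidosis against 58.9% of all listed genes. The test does not match members for level, so it cannot tell a list effect from a level effect. Heat shock chaperones, which refold damaged proteins, were listed higher in every treatment: of 21 genes, 14 were higher and 1 lower in lactic acidosis (adjusted p = 0.0105), 15 and none in lactosis (adjusted p = 0.00191) and 14 and none in acidosis (adjusted p = 0.00280, all by Fisher's exact test). HSPA8, the constitutive cytosolic chaperone, averaged 825 ± 302 (SD, n = 3) in control, 1999 ± 121 (SD, n = 3) in lactic acidosis, 2363 ± 188 (SD, n = 3) in lactosis and 1675 ± 53.5 (SD, n = 3) in acidosis. HSPA2 averaged 3.73 ± 1.57 (SD, n = 3) in control and 17.3 ± 0.728 (SD, n = 3) in lactic acidosis. DNAJA1 and HSPH1 had log2 fold changes of 1.31 and 1.09 in lactic acidosis in the authors' deposited table. The member listed lower was HSPB1, at -1.79 in the authors' deposited table.

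Of 30 genes of ribosome biogenesis, 20 were listed higher in lactic acidosis (adjusted p = 2.57e-04) and 17 in lactosis (adjusted p = 8.15e-04), and none lower. In acidosis 4 were listed higher and none lower, without a call (adjusted p = 0.185, all by Fisher's exact test). Without control replicate 1, 19 of the 20, 13 of the 17 and 0 of the 4 passed limma. Between treated groups, limma found 2 of 13 members tested higher in lactic acidosis than in lactosis, 2 of 3 higher in lactic acidosis than in acidosis and 1 of 4 higher in lactosis than in acidosis, and after rescaling to the authors' size factors 1 in each. NCL, which encodes nucleolin, averaged 781 ± 166 (SD, n = 3) in control, 1240 ± 76.7 (SD, n = 3) in lactic acidosis and 1092 ± 116 (SD, n = 3) in lactosis. URB2 and NOLC1 had log2 fold changes of 1.19 and 0.91 in lactic acidosis in the authors' deposited table. PPARGC1A, a coactivator of mitochondrial genes, averaged 3.46 ± 0.954 (SD, n = 3) in control, 0.433 ± 0.0950 (SD, n = 3) in lactic acidosis, 0.210 ± 0.0529 (SD, n = 3) in lactosis and 0.623 ± 0.126 (SD, n = 3) in acidosis.

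Of the 1034 genes with 1 direction in all 3 tables, the change in lactic acidosis was smaller than the sum of the changes in lactosis and acidosis in 974 (94.2%), with a median ratio of 0.61. The shared controls enter this sum more than once, so the ratio is given as a value only.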
